A study of Mus musculus with 8 samples.

How the data were processed

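EL08-1D2, a mouse stromal cell line, was grown alone or for 5 days under primary human B cells of chronic lymphocytic leukaemia (CLL). CLL is a cancer of mature B lymphocytes. The series holds 8 arrays, 2 of mono-cultures and 6 of co-cultures, each co-culture with CLL cells of a different donor. Per the labels' protocols, the CLL cells were washed off, remaining ones were removed with magnetic beads against CD19, and RNA of the stromal cells was extracted. The labels do not state whether the mono-cultures went through the same washing and bead steps. Per the labels' protocols, biotin-labelled cRNA was made from 200 ng of total RNA and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, a 1-colour platform on which each probe set reports 1 transcript or a part of it.

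The deposited values are linear intensities, 1 signal per probe set and array, made with MAS5 per the submitters' processing notes. The version of MAS5 and its settings are not given in the sources used here. On each of the 8 arrays the mean signal without the lowest and highest 2% of probe sets was 1000.01, so each array had been scaled to a common trimmed mean. No detection call was used, and depth has no meaning for arrays, so the number of arrays limits the precision. The table holds 45101 probe sets, of which 64 are Affymetrix controls. In the platform annotation, 34945 of the others have 1 gene symbol, 932 have several and 9160 have none. Of the probe sets with 1 symbol, 34741 have a symbol found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols were changed by it. Genes are named by the annotation's symbols, and no gene is named from a probe set with several. The annotation names no genome build for these files, so no coordinates are given.

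Signals were transformed as log2(signal + 46), where 46 is the 25th percentile of all signals. This offset shrinks the fold changes of dim genes, and all log2 differences and folds below are on this scale. A probe set was kept if its signal was above the median of its array on at least 2 of the 8 arrays, which kept 24430 probe sets, 20653 of them with 1 gene symbol. Each gene was represented by its kept probe set with the highest mean over the 8 arrays, giving 11245 genes. Co-cultures were compared with mono-cultures by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance over the mean, two-sided) with Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. The co-culture numbers follow the order of the samples and pair nothing. The labels do not say whether the 2 mono-cultures are separate cultures, so p-values measure the spread between these arrays. The spread between donors and the spread between arrays cannot be separated, since no donor was used more than once.

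Before the data were examined, 22 gene lists and 8 lists of cell type markers were fixed, together with the tests, the alternatives and the rule for named genes. The gene lists cover the PKC family, NF-kB components and feedback genes, chemokines, cytokines and growth factors, interferon-stimulated genes, the MHC class I pathway, complement and acute phase, collagens and matrix, contractile and TGF-beta-induced genes, proteases and inhibitors, adhesion molecules and integrins, haematopoietic niche factors, Notch and Wnt response, adipogenic and osteogenic genes, cell cycle, p53 targets and growth arrest, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein response with ATF4 targets, oxidative stress response, ribosomal proteins and oxidative phosphorylation. The marker lists cover B cells, all leukocytes, MHC class II, monocytes and macrophages, T and NK cells, erythroid cells and platelets, endothelium and stroma. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists, beside camera with an estimated correlation and fry. camera asks whether a list's genes moved more than the other genes. fry asks whether they moved, on balance, one way (or, as its mixed test, in either direction), without a comparison with other genes. A list's score on an array is the mean log2 value of its measured genes less the mean of the mono-cultures.

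The rule named up to 15 genes per direction, those past the threshold with the largest log2 difference, with all 6 co-cultures beyond both mono-cultures and with a mean in the higher group above the array-wide median. It also named every measured member of the PKC family, and in each list the 4 largest members past the threshold or, with none, the 2 with the largest difference, given as values. Predicted genes without a given name were passed over, and a few genes of the sex chromosomes were left out. It gave 62 genes, and 20 more were named after their values were seen, which the text marks. A single value was compared between the groups by an exact permutation test over the 28 splits of the 8 arrays, whose smallest possible two-sided p is 0.0714.

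The gene and list tests were tested on simulated data with the means and spreads of the 11245 genes and 2 against 6 arrays. Of 100 genes changed 2-fold, 68% were recovered, and of 100 changed 4-fold, 98%. The changed genes were drawn at random, and each gene's simulated spread was averaged with the trend of spread over the mean. These shares therefore do not hold for genes that vary widely among the co-cultures. Mmp13, for example, differed 14.3-fold in the real data and did not pass limma's test (adjusted p = 0.363). Of 182 calls, 16 were false, and 5 of 100 unchanged lists had a camera p under 0.05. Noise was drawn independently for each gene, and the unchanged lists were random genes. The simulation therefore does not test camera on lists with correlated genes, such as NF-kB or cell cycle (estimated correlations 0.38 and 0.57). Alternatives covered quantile normalization, median centring, no offset, an offset of 167, no filter, a stricter filter on the mean (60th percentile), eBayes without trend or with robust estimation, the mean of a gene's probe sets, every probe set on its own, leaving out probe sets ending in _x_at or _s_at, array weights, and leaving out each array in turn. Without 1 mono-culture, the other one is assumed to vary like the co-cultures. Figures were drawn with matplotlib 3.10.9.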

Results

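Gene expression was measured on 8 arrays of the mouse stromal cell line EL08-1D2, 2 of cells grown alone and 6 of cells grown for 5 days with CLL B cells of a different donor each. The comparison asks which stromal genes differ after contact with leukaemic B cells. PKC-beta, the product of Prkcb, is the signalling kinase at the centre of the known work on this system. The median signal per array lay between 161 and 173 arbitrary units. Over the 24430 kept probe sets, the 2 mono-cultures correlated at r = 0.972, pairs of co-cultures at 0.947 to 0.986, and mono-cultures with co-cultures at 0.950 to 0.975. These correlations are across probe sets, which are not independent replicates. The 3 control probe sets for 18S ribosomal RNA were lower in all 6 co-cultures, with log2 differences of -0.72, -1.25 and -1.08, each with an exact permutation p of 0.0714, the smallest that 2 against 6 arrays can give. The 3'/5' signal ratio of beta-actin, a measure of RNA integrity, was 1.26 and 1.49 in the mono-cultures and 1.39 to 1.67 in the co-cultures.

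The genes that rose in co-culture include several of surface and secreted proteins with known parts in adhesion and the matrix. The lists of adhesion molecules and of matrix genes did not pass camera as groups. They passed fry's mixed test of movement in either direction (adjusted p = 6.47e-04 and 0.0138). Vcam1 and Dcn are the only members of these lists past the threshold, and the mixed test was not run without them. Vcam1, the adhesion receptor that binds leukocyte integrins, rose 2.11-fold, from a mean signal of 8742 in the 2 mono-cultures to 18583 ± 1740 (SD, n = 6) in the co-cultures. Has2, which makes hyaluronan, rose 4.24-fold, from 604 to 2508 ± 160 (SD, n = 6), and Dcn, the collagen-binding proteoglycan decorin, rose 2.31-fold, from 16694 to 38029 ± 3154 (SD, n = 6). Steap4, a metalloreductase induced in inflammation, rose 9.55-fold, from 252 to 2852 ± 1451 (SD, n = 6). Tnn, which encodes the matrix protein tenascin-N, fell from 701 to 46.5 ± 40.8 (SD, n = 6). That level lies below the array medians and near the offset added before the logarithm, so the size of the 8.75-fold difference depends on the offset, and without the offset Tnn did not pass (log2 -4.53, adjusted p = 0.180).

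In all, 12 of 11245 genes passed the threshold in limma's test, 9 higher and 3 lower in co-culture, of which 8 and 2 differed at least 2-fold. The other genes that rose were Fas, the death receptor, 3.72-fold (log2 1.90, SE 0.25, adjusted p = 0.0401), Prelp, a leucine-rich matrix protein, 2.59-fold (log2 1.37, SE 0.17, adjusted p = 0.0298), and Fst, the activin-binding follistatin, 2.51-fold (log2 1.33, SE 0.18, adjusted p = 0.0401). Nrip1, a nuclear receptor corepressor, rose 2.0-fold and Fbxl5, the iron-sensing subunit of a ubiquitin ligase, rose 1.72-fold, with adjusted p of 0.0401 and 0.0458. Adjusted p was 0.0264 for Vcam1 (log2 1.08, SE 0.11), 0.0298 for Has2 (log2 2.08, SE 0.24) and Dcn (log2 1.21, SE 0.15), and 0.0458 for Steap4 (log2 3.26, SE 0.46). Besides Tnn (log2 -3.13, SE 0.42, adjusted p = 0.0401), the lipid-transfer protein gene Stard10 fell 2.78-fold (log2 -1.47, SE 0.21, adjusted p = 0.0458). The third gene that fell, the predicted gene Gm41724, went down 1.99-fold (log2 -0.99, SE 0.14, adjusted p = 0.0462) and is named after its values were seen. For each of the 12 genes, all 6 co-cultures lay beyond both mono-cultures. Dcn, Fst, Has2, Nrip1 and Vcam1 had further kept probe sets, and all of these went in the same direction.

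**Figure D1:**
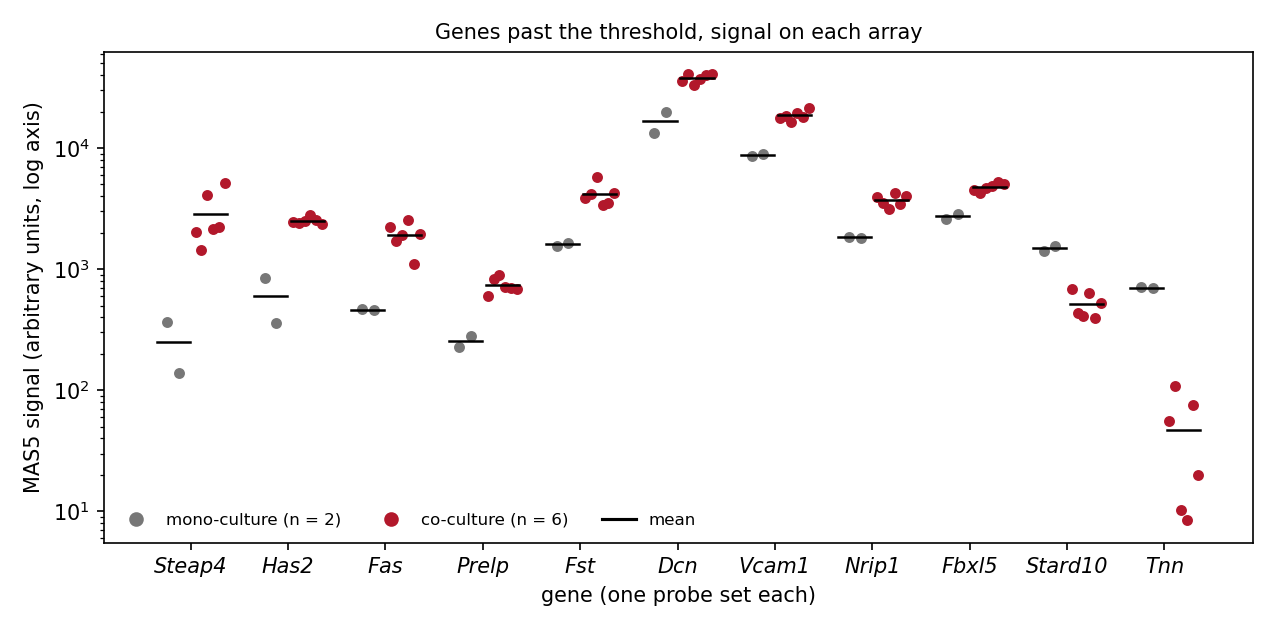
MAS5 signal (arbitrary units, log axis) of the 11 named genes past the threshold, 1 probe set each, with grey points for the 2 mono-cultures, red points for the 6 co-cultures and black bars for the means. All 6 co-cultures lie above both mono-cultures for the 9 genes from Steap4 to Fbxl5 and below both for Stard10 and Tnn.

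At an unadjusted p under 0.05, 1088 genes differed, 637 higher and 451 lower, where chance gives 562. All 6 co-cultures lay above both mono-cultures for 656 genes (5.83%) and below both for 668 (5.94%), where chance gives 3.57% in each direction. The calls changed with single arrays, while the log2 differences of the 12 genes stayed within 0.723 to 1.28 times their values with all arrays. Without co-culture 1 or without co-culture 4 no gene passed in limma's test (982 and 837 genes at an unadjusted p under 0.05), without co-culture 6 only 1 did, and without either mono-culture 3 (mono-culture 1) and 5 (mono-culture 2) did. Without co-culture 3 the count was 6, without co-culture 2 it was 16 and without co-culture 5 it was 13. Stard10 and Gm41724 passed under none of the 8 left-out arrays, and Fbxl5 and Steap4 under 1 each.

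Genes of NF-kB signalling, the transcription factor pathway that drives inflammatory genes, were higher as a group. The list's score was 0.93 and 0.98 in co-cultures 3 and 6 and 0.37 to 0.63 in the other 4, above both mono-cultures in all 6. Of 22 measured components and feedback genes, 19 were higher in co-culture, with a median log2 difference of 0.53. Besides Vcam1, none passed over all genes tested, while 10 passed, all higher, when adjusted over the list alone. Among these, named after their values were seen, were the kinase gene Map3k8 (log2 2.07, SE 0.34) and the survival factor gene Birc3 (1.07, SE 0.22). The NF-kB regulator genes Nfkbiz (1.60, SE 0.42) and Nfkbie (1.47, SE 0.29), also named afterwards, were among them too. Each of these named genes was above both mono-cultures in all 6 co-cultures. Without co-culture 2, Map3k8 passed over all genes (adjusted p = 0.0294). The list passed limma's camera test at the preset correlation (adjusted p = 4.39e-11), but not with the correlation estimated from these arrays (adjusted p = 0.197 with an estimated correlation).

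Secreted inflammatory products were higher as groups as well. Of 15 complement and acute-phase genes, 14 were higher, with a median log2 difference of 0.41 and a mean of 1.44 (camera adjusted p = 4.50e-06, and adjusted p = 0.197 with an estimated correlation). When adjusted over the list alone, 3 passed, Steap4 and, named after their values were seen, the protease inhibitor gene Serpina3n (2.75, SE 0.71) and the copper carrier gene Cp (1.72, SE 0.49). Of 34 cytokines and growth factors, 24 were higher (median 0.31, camera adjusted p = 6.17e-04, and adjusted p = 0.197 with an estimated correlation), and 8 lay above both mono-cultures in all 6 co-cultures. Over all 44 on the array, without the filter, the median was 0.19, with 29 higher and 15 lower. Il6, the cytokine that induces acute-phase genes, had the largest difference in that list, from 266 to 4461 ± 4765 (SD, n = 6), with an adjusted p of 0.324, and the alarmin gene Il33 had a log2 difference of 1.32 (SE 0.41). Il33 had signals of 511 and 158 in the mono-cultures, and 5 of 6 co-cultures lay above both. Of 19 chemokines, 14 were higher (median 0.68, camera adjusted p = 8.97e-04, and adjusted p = 0.198 with an estimated correlation). Without the filter, the median over all 30 on the array was 0.19, with 20 higher and 10 lower. The chemokine score lay above both mono-cultures in 5 of 6 co-cultures. The neutrophil chemoattractant gene Cxcl5 (1.73, SE 0.84) and the lymphocyte chemoattractant gene Cxcl10 (1.49, SE 0.45) did not pass. For Cxcl5 the mono-cultures were far apart (signals 10198 and 2501), with 4 of 6 co-cultures above both, against 6 of 6 for Cxcl10. Without mono-culture 2 the chemokine list was no longer called by camera (mean log2 difference 0.19 against 0.54 with all arrays, adjusted p = 0.333), and without mono-culture 1 its mean was 0.88 (adjusted p = 4.72e-05).

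Proteases and their inhibitors were also higher, 19 of 24 with a median log2 difference of 0.31 (camera adjusted p = 8.97e-04, and adjusted p = 0.197 with an estimated correlation). The collagenase gene Mmp13 (3.84, SE 1.25) and the protease inhibitor gene Serpinb2 (3.46, SE 1.15) had the largest differences without passing, and the stromelysin gene Mmp3 (1.30, SE 0.25), named after its values were seen, passed when adjusted over the list alone. Of 20 haematopoietic niche factors, the products by which stroma supports blood cells, 16 were higher (median 0.29, camera adjusted p = 6.17e-04, and adjusted p = 0.197 with an estimated correlation), and Vcam1 was the only member past the threshold. Without the filter, the median over all 25 niche factors on the array was 0.15, with 17 higher and 8 lower. This list shares 5 genes with the cytokines. Of 30 targets of the unfolded protein response and ATF4, which act on protein folding stress in the endoplasmic reticulum, 24 were higher (median 0.19, camera adjusted p = 6.17e-04, and adjusted p = 0.488 with an estimated correlation). The chaperone gene Dnajb9 (0.83, SE 0.20) and, named after their values were seen, Pdia4 (0.67, SE 0.16) and the transcription factor gene Xbp1 (0.48, SE 0.08) passed when adjusted over the list alone, as did the stress-induced mTOR inhibitor gene Ddit4, also named afterwards, which was lower (-0.70, SE 0.13). Without _x_at and _s_at probe sets, another probe set stood for Xbp1, with a difference of 0.93 that passed over all genes (adjusted p = 0.0366). Stc2 had a log2 difference of 0.85 (SE 0.37), and 1 of its 3 kept probe sets went the other way. The MHC class I pathway, which presents antigen to T cells, was higher in 12 of 15 genes (median 0.33, camera adjusted p = 0.0430, and adjusted p = 0.701 with an estimated correlation), with Psmb8 at 0.88 (SE 0.53) and H2-K1 at 0.53 (SE 0.39). The score of the MHC class I list lay above both mono-cultures in 3 of 6 co-cultures and below both in 1, and that of the unfolded protein response list above both in 4 of 6. By camera's adjusted p, the protease list was not called without mono-culture 1 (0.172), although its mean was 0.56 against 0.57 with all arrays, and the MHC class I list was not called without mono-culture 1 (0.604, mean 0.14 against 0.27 with all arrays) or co-culture 1 (0.174), 2 (0.215, mean 0.16) or 4 (0.0557), with the stricter filter, with eBayes without trend, or without _x_at and _s_at probe sets. The mean of the unfolded protein response list, 0.21 with all arrays, was 0.086 without mono-culture 1, 0.34 without mono-culture 2 and 0.14 without co-culture 6, and the list stayed called.

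Most measured genes of energy metabolism lists were lower, by small amounts. Of 27 oxidative phosphorylation genes, 24 were lower and 11 lay below both mono-cultures in all 6 co-cultures, with a median log2 difference of -0.17 (camera adjusted p = 1.45e-06, and adjusted p = 0.197 with an estimated correlation). Cox5a, a subunit of cytochrome c oxidase, had a difference of -0.38 (SE 0.10) and Sdhc, a subunit of succinate dehydrogenase, -0.38 (SE 0.14). Of 27 hypoxia and glycolysis genes, 23 were lower (median -0.16, camera adjusted p = 0.00134, and adjusted p = 0.210 with an estimated correlation), while the 2 with the largest differences were higher, the angiogenic factor gene Vegfa (0.71, SE 0.36) and Pfkfb3, a regulator of glycolysis (0.48, SE 0.17). Of 20 cholesterol synthesis genes, 18 were lower (median -0.39, camera adjusted p = 8.39e-04, and adjusted p = 0.526 with an estimated correlation), with Mvd at -0.74 (SE 0.33) and Hsd17b7 at -0.68 (SE 0.38). The cholesterol synthesis score lay below both mono-cultures in 4 co-cultures (-0.35 to -0.67) and above both in co-cultures 2 (0.14) and 6 (0.063), and no member was below both mono-cultures in all 6. The hypoxia score lay below both mono-cultures in 4 of 6 co-cultures and the ribosomal protein score in 2 of 6, with the others in between. Of 21 ribosomal proteins, 19 were lower by little (median -0.055, camera adjusted p = 0.0460, and adjusted p = 0.701 with an estimated correlation), with Rps6 at -0.42 (SE 0.20) and Rpl14 at -0.32 (SE 0.15). The signal of 18S ribosomal RNA was lower in all 6 co-cultures, including co-culture 1, whose ribosomal protein score was the highest of the 6 (0.0033). Without mono-culture 2 the hypoxia list was not called (mean -0.067 against -0.14 with all arrays, camera adjusted p = 0.0594), and without mono-culture 1 its mean was -0.21. The call of the ribosomal proteins was lost without mono-culture 2, where the mean turned (0.012 against -0.085, camera adjusted p = 0.309), without co-culture 2, 3, 4 or 5 (0.152, 0.0637, 0.0577 and 0.0913 as adjusted p), and in 7 processing settings such as quantile normalization (adjusted p = 0.582), while without mono-culture 1 the mean was -0.18.

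Most measured genes of the proliferation and contractile lists were lower too, but not in every co-culture. Of 43 cell cycle genes, 36 were lower (median -0.22, camera adjusted p = 0.00588, and adjusted p = 0.739 with an estimated correlation). The list's score lay below both mono-cultures in 5 of 6 co-cultures and above both in co-culture 2. The proliferation marker gene Mki67 had a difference of -0.59 (SE 0.34) and the mitotic cyclin gene Ccnb2 -0.52 (SE 0.31). Of 23 contractile and TGF-beta-induced genes, 15 were lower (median -0.15, camera adjusted p = 0.0231, and adjusted p = 0.273 with an estimated correlation). The score of this list lay below both mono-cultures in 1 of 6 co-cultures and between them in the other 5. Tagln, an actin-binding protein of smooth muscle (-1.21, SE 0.31), passed when adjusted over the list alone. So did Tpm2, a tropomyosin (-0.50, SE 0.10) named after its values were seen. The matrix protein gene Ltbp2 had the opposite sign (2.24, SE 0.85), with mono-culture signals of 96.4 and 83.9, below the array medians. The cell cycle list was not called without mono-culture 1 (camera adjusted p = 0.195) or co-culture 5 (mean -0.10 against -0.20 with all arrays, adjusted p = 0.115), and its mean was -0.31 without co-culture 2. The mean of the contractile list, -0.040, was -0.16 without mono-culture 1, and the call was lost without mono-culture 2 (mean 0.081, camera adjusted p = 0.391), without co-culture 5 (mean -0.014, adjusted p = 0.0516) and with the stricter filter (mean 0.038, adjusted p = 0.0648).

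**Figure D2:**
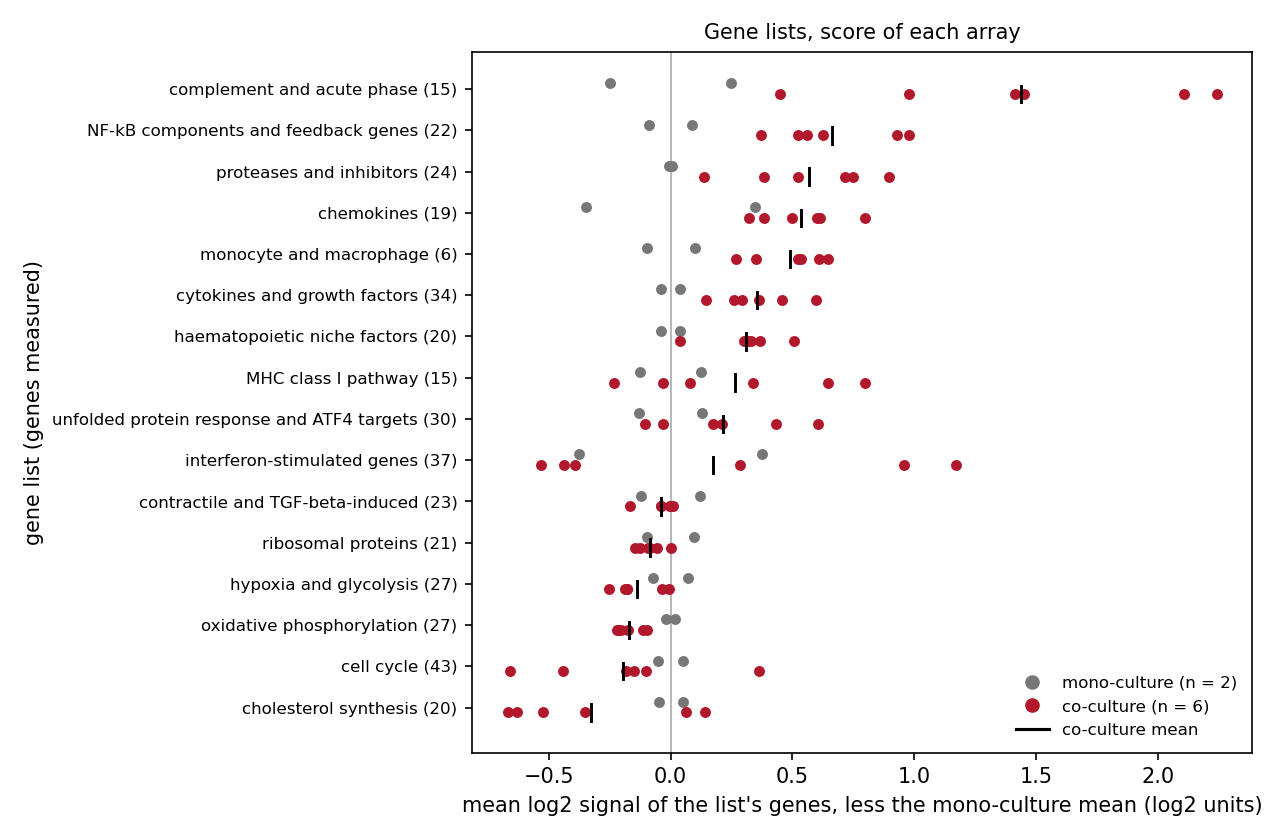
Score of each array for the 15 lists that passed camera at the preset correlation and for the interferon-stimulated genes, as the mean log2 signal of the list's measured genes (their number in brackets) less the mono-culture mean, with grey points for the 2 mono-cultures, red points for the 6 co-cultures and black bars for the co-culture mean. Scores of the acute-phase list run from 0.45 to 2.24 in the co-cultures, while those of the interferon-stimulated genes lie on both sides of 0, from -0.53 to 1.17.

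The other gene lists did not pass camera with all arrays. Interferon-stimulated genes had a median log2 difference of 0.14 over 37 genes (camera adjusted p = 0.160), with the antiviral gene Rsad2 at 1.03 (SE 0.68) and the GTPase gene Gbp2 at 1.02 (SE 0.30). This list was called by camera, as higher, without mono-culture 2 (mean 0.55, adjusted p = 7.69e-04), without co-culture 3 (0.0231), 5 (0.00732) or 6 (0.0184) and with array weights (0.0227), while its mean turned without mono-culture 1 (-0.20, adjusted p = 0.588) and without co-culture 2 (-0.024, adjusted p = 0.962). Without mono-culture 1 the collagens and matrix list was called, as lower (mean -0.18, adjusted p = 0.0398), and without co-culture 6 the oxidative stress list was, as lower (mean -0.089, adjusted p = 0.0354). Collagens and matrix genes had a median of -0.082, with Dcn higher, and Col12a1, named after its values were seen, lower (-0.77, SE 0.15) and past the threshold when adjusted over the list alone. Adhesion molecules and integrins had a median of 0.022, with Vcam1 the only member past the threshold. The p53 and growth arrest genes had a median of -0.16 and a mean of 0.021. Fas was higher in that list, while Cdkn2a, which encodes cell cycle inhibitors and is named after its values were seen, was lower (-0.80, SE 0.20) and passed when adjusted over the list alone. Notch and Wnt response genes had a median of 0.040, with Lef1 at 0.61 (SE 0.26) and Heyl at 0.42 (SE 0.34). Adipogenic and osteogenic genes had a median of 0.098, with Cebpd at 1.5 (SE 0.41), past the threshold when adjusted over the list alone, and Fabp4 at -0.60 (SE 0.44). Oxidative stress genes had a median of -0.088, with the metallothionein gene Mt2 at 1.38 (SE 0.58) and the glutathione transferase gene Gsta4 at -1.01 (SE 0.40). Mt2 had signals of 6700 and 1770 in the mono-cultures, and 4 of 6 co-cultures lay above both.

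No rise of Prkcb RNA was detectable on these arrays. Its 3 probe sets were above the array median on 0 of 8 arrays, between the 1.49th and the 36.8th percentile, and so were not part of the gene test. Probe set 1460419_a_at, which has the highest mean, had a signal of 37.4 in mono-culture and 56.0 ± 13.2 (SD, n = 6) in co-culture, a log2 difference of 0.29 with an adjusted p of 0.786 in limma's test without the filter. It lay above both mono-cultures in 4 of 6 co-cultures and below both in 0. Probe set 1423478_at was lower, at 79.5 and 17.8 ± 11.2 (SD, n = 6), below both mono-cultures in 6 of 6 co-cultures, with a log2 difference of -0.99 and an adjusted p of 0.222 over all probe sets. Probe set 1443144_at had signals of 20.4 and 10.8 ± 8.48 (SD, n = 6) and a log2 difference of -0.22. The sign of the gene's value thus depended on the probe set, and the mean over all 3 was -0.31.

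**Figure D3:**
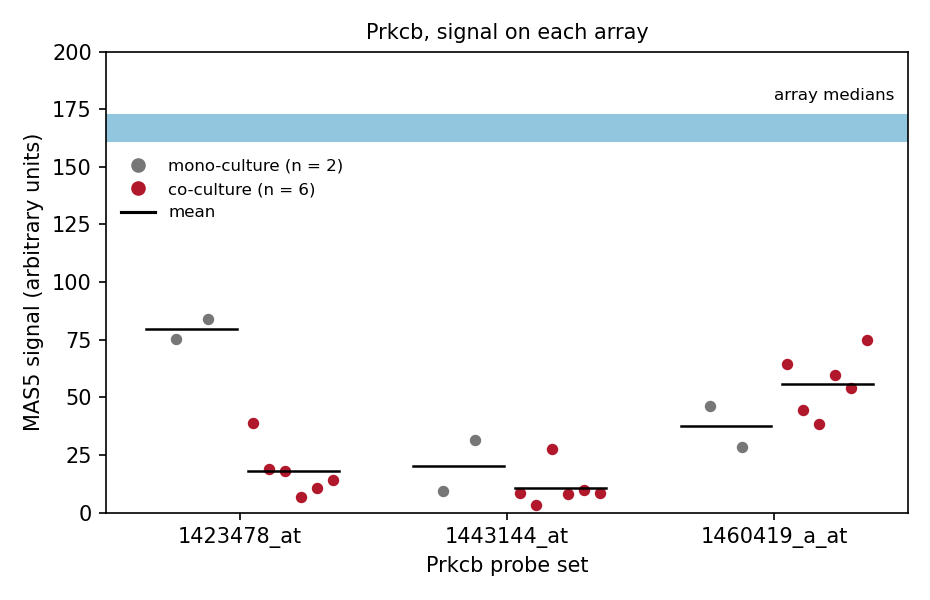
MAS5 signal (arbitrary units) of the 3 Prkcb probe sets, with grey points for the 2 mono-cultures, red points for the 6 co-cultures, black bars for the means and a blue band for the range of the array medians, 161 to 173. All points lie below the band.

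Of the PKC family, 7 members were measured above the filter and none passed, with a median log2 difference of 0.051 (camera adjusted p = 0.599). Prkcd had the largest difference (0.37, SE 0.18) and was above both mono-cultures in 6 of 6 co-cultures, followed by Prkd2 (0.20, SE 0.13). The differences were 0.056 for Prkd3, 0.051 for Prkce, -0.079 for Prkca, -0.087 for Prkci and -0.091 for Prkd1. A second kept probe set of Prkca and one of Prkcd had the opposite sign.

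Markers of other cell types were mostly at low signals. The CLL cells were human and the probe sets are for mouse genes, so these markers do not measure CLL RNA directly. Of 23 B cell markers on the array, 6 passed the filter, with a median log2 difference of 0.24 (camera adjusted p = 0.368). Cd24a (-1.0, SE 0.34) was lower and Ebf1 (0.65, SE 0.19), named after its values were seen, was higher, both past the threshold when adjusted over the list alone, and Spib had a difference of 0.90 (SE 0.36). Of 25 pan-leukocyte markers, 11 passed the filter, with a median of 0.0034 and a mean of -0.0078, including Ptprcap at -0.63 (SE 0.63) and Fermt3 at 0.29 (SE 0.22), and the list did not pass (camera adjusted p = 0.799). Of 25 monocyte and macrophage markers on the array, 6 passed the filter, and all 6 were higher (median 0.47, camera adjusted p = 0.0330, and adjusted p = 0.197 with an estimated correlation). Without the filter, the median over all 25 was 0.061, with 17 higher and 8 lower. The macrophage pore protein gene Mpeg1 was at 0.99 (SE 0.58), above both mono-cultures (signals 65.2 and 374) in 2 of 6 co-cultures. The endotoxin co-receptor gene Cd14 was at 0.82 (SE 0.61), above both mono-cultures (974 and 384) in 3 of 6. The measured markers moved in the same direction as the NF-kB and acute-phase lists. This list was not called without mono-culture 1 (camera adjusted p = 0.196), without co-culture 1 (0.0546), without the filter (mean 0.18 against 0.49), with the stricter filter or without _x_at and _s_at probe sets. The 2 measured MHC class II genes were H2-DMa (-0.57, SE 0.19), past the threshold when adjusted over the list alone, and Cd74 (-0.17, SE 0.24), with a camera adjusted p of 0.106. Erythroid and platelet markers had a median of -0.41, with Pf4 at -0.41 (SE 0.22) and Ppbp at -0.59 (SE 0.50). T and NK cell markers had a median of -0.039 and a mean of 0.21, with Zap70 at 1.35 (SE 0.59; 2.82 and past the threshold without mono-culture 2, adjusted p = 0.0317) and Lat at -0.44 (SE 0.53). Endothelial markers had a median of -0.100, with Plvap at 0.46 (SE 0.20) and Egfl7 at -0.36 (SE 0.21), 1 of whose 3 kept probe sets went the other way. The 16 measured stromal markers had a median of 0.032, and none of these last 4 lists passed camera with all arrays. Without mono-culture 2, the mean of the stromal list was 0.27.

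Of the 30 lists, 15 passed camera at the preset correlation, 9 higher and 6 lower. With an estimated correlation 0 passed (7 at an unadjusted p under 0.05), and by fry's test of one direction 0 passed (10 at an unadjusted p under 0.05), while fry's mixed test passed 11. These 11 include lists that did not pass camera. They are adhesion molecules and p53 targets (mixed adjusted p = 6.47e-04 each), and collagens and stromal markers (0.0138 each). Each of these holds 1 gene past the threshold (Vcam1, Fas, Dcn and again Dcn), and the mixed test was not run without it.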

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

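The tests in this part were fixed before the data were examined, apart from those on 20 genes, Ebf1 and Gm41724 among them, which were chosen after their values were seen. For each of 112 values (82 named genes and 30 list scores), the gap between the most extreme of the 6 co-cultures and its nearest neighbour was divided by the range of the 6. Above Dixon's 95% critical value for 6 values lay 7 of them, where chance gives 5.6, so the count as a whole is about what chance gives. Co-culture 2 was highest for Ptprcap (ratio 0.743) and lowest for Ppbp (0.680). Co-culture 5 was highest for the endothelial marker gene Plvap (0.709) and lowest for the score of the contractile and TGF-beta-induced list (0.727). Co-culture 3 was lowest for the score of the stromal markers (0.673), and co-culture 6 was lowest for Ebf1 (0.717) and highest for the predicted gene Gm41724 (0.657). No explanation of these single values was tested.

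Outside the gene test, 3777 kept probe sets have no gene symbol or several. limma's test on these alone passed 2, both higher in co-culture. Probe set 1423954_at had a log2 difference of 1.83 (SE 0.21, adjusted p = 0.00680), and probe set 1441304_at one of 3.27 (SE 0.47, adjusted p = 0.0354). Their genes are not named here.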

How the results depend on the processing

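The alternatives were fixed before the data were examined, and no paired analysis was possible because the co-culture numbers pair nothing. The median difference of all genes stayed within 0.017 of 0 under each scaling. Of 1623 values of 82 named genes under 12 processing settings and 8 left-out arrays, 1507 kept their direction and side of the threshold, 104 lost and 3 gained a call, and 9 turned. All 104 losses fell on the 12 genes called with all arrays and the main processing, since only a called gene can lose its call. Most of the values that kept their side were of genes never called. The stricter filter gave no value for 13 of the genes, Tnn and Tagln among them, and none for the MHC class II list, and 4 genes, Prelp among them, have none without _x_at and _s_at probe sets. The lists were not tested on all probe sets. Vcam1 passed in 12 of 12 processing settings and 4 of 8 left-out-array settings, Has2 in 11 and 5, Prelp in 10 and 3, Fas in 10 and 2, Dcn in 9 and 4, Fst in 9 and 3, Tnn in 9 and 2, Nrip1 in 8 and 3, Steap4 in 8 and 1, Fbxl5 in 7 and 1, Gm41724 in 7 and 0, and Stard10 in 6 and 0. Of the 15 lists called, 7 stayed called in all 19 settings (NF-kB, cytokines, complement and acute phase, niche factors, cholesterol synthesis, unfolded protein response and oxidative phosphorylation). With an estimated correlation and with fry's test of one direction, 0 lists were called. Of the 15 others, 4 were called in some setting, the interferon-stimulated genes in 5 of 19 and the collagens, oxidative stress and stromal lists in 1 each.

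The 9 genes higher in co-culture became 4 with eBayes without trend and 1 when all 20653 kept probe sets were tested, and the 8 at least 2-fold higher became 4 and 1. The 3 genes lower became 1 with median centring and with array weights, 0 without an offset and with all probe sets, and 5 with the mean of a gene's probe sets. The 2 at least 2-fold lower became 1 with median centring, the stricter filter, eBayes without trend and array weights, and 0 without an offset and with all probe sets. Leaving out each array gave 0 to 15 genes higher, 0 to 2 lower, 0 to 12 at least 2-fold higher and 0 to 2 at least 2-fold lower. The 0 calls came without co-culture 1 or 4, and the 15 higher without co-culture 2, where 10 of the 12 genes remained. Without co-culture 5, 13 genes were called, 8 of them among the 12. Prkcb moved from 0.29 to 0.59 without an offset, which weighs dim signals more, and to -0.31 with the mean of its probe sets. The other causes were not tested.

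None of the values whose mean or tested direction turned was called with all arrays and the main processing, apart from the ribosomal proteins and the contractile list, whose mean (-0.040) was 0.038 with the stricter filter and ran from -0.16 to 0.081 over the left-out arrays. Under processing settings these were collagens (0.019, quantile normalization), endothelial markers (-0.010 with median centring, 0.18 with the stricter filter, 0.19 without _x_at and _s_at probe sets, -0.0013 with array weights), Notch and Wnt genes (-0.061 without the filter, -0.048 with the stricter one), erythroid and platelet markers (0.040 without the filter), B cell markers (-0.14, stricter filter), Prkca (0.017, mean of probe sets), and Egfl7 (0.22) and pan-leukocyte markers (-0.046) without _x_at and _s_at probe sets. Over the left-out arrays the values ran from -0.36 to 0.18 for Prkd1, -1.72 to 0.46 for Ptprcap, -0.12 to 2.82 for Zap70, -1.55 to 0.37 for Ppbp, -0.26 to 0.10 for Prkca, -0.39 to 0.048 for Cd74 and -2.30 to 0.73 for Ifi27l2a. List means ran from -0.20 to 0.55 for interferon-stimulated genes, -0.092 to 0.15 for adhesion molecules, 0.0021 to 0.073 for Notch and Wnt genes, 0.054 to 0.25 for adipogenic and osteogenic genes, -0.18 to 0.60 for T and NK cells, -0.094 to 0.091 for endothelium, -0.062 to 0.27 for stroma, -0.18 to 0.15 for collagens, -0.072 to 0.12 for p53 targets, -0.18 to 0.012 for ribosomal proteins and -0.12 to 0.10 for pan-leukocyte markers. The turns came mostly from leaving out a mono-culture, which leaves 1 array in that group. Signals below the array medians, as for Prkcb, limit what can be said of dim genes.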

Other observations

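In this part, the tests by splits of the arrays, of scaling as an explanation of the NF-kB list, of leukocyte RNA, of the spread between mono-cultures, of the 18S signal and of the acute-phase score against the interferon score were chosen after the results were seen.

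Acute-phase genes varied widely among the co-cultures. The first principal component of the 11245 genes over all 8 arrays held 34.2% of the variance and was led by Lcn2, Hp and Saa3, acute-phase genes named after their values were seen. Lcn2 ranged from 52.7 in co-culture 2 to 32817 in co-culture 6, against 148 and 29.7 in the mono-cultures, and Saa3 from 720 to 57056, against 2037 and 235. Their log2 differences of 4.51 (SE 1.90) and 3.77 (SE 1.45) did not pass, with adjusted p of 0.488 and 0.453. At the other end of the component lay the interferon-induced gene Ifi27l2a, from 350 in co-culture 6 to 9759 in co-culture 2, against 659 and 5690 in the mono-cultures. The acute-phase score was 0.98, 0.45, 2.11, 1.41, 1.45 and 2.24 in co-cultures 1 to 6, and the interferon score 0.96, 1.17, -0.39, 0.29, -0.53 and -0.44.

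Across the 6 co-cultures, the acute-phase and interferon scores ran in opposite directions, with r = -0.878 (exact permutation p = 0.0292, 0.0875 after adjustment over the 3 relations computed, so chance is not excluded) and Spearman's rho = -0.829 (exact permutation p = 0.0583). Without co-cultures 2 and 6, the 2 farthest from the median acute-phase score, r was -0.764. RNA quality stays open as a source of the acute-phase spread, since the score had r = 0.483 with the log2 actin 3'/5' ratio (exact permutation p = 0.393, rho = 0.257, exact permutation p = 0.658), between the bounds set for and against it. Variation that also arises without CLL cells stays open too, since the mono-cultures differed by 0.497, which is 0.520 of the SD of a difference between 2 co-cultures, and their interferon scores differed by 0.75. Differences between the donors' CLL cells also stay open, untested, since no donor was repeated.

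Chance cannot be excluded for the higher NF-kB list, the counts of genes or the number of lists called. Of the 28 splits of the 8 arrays into 2 and 6, 2 called at least 12 genes, the real one with 12 and that of mono-culture 2 and co-culture 2 against the rest with 13, and 3 had at least the 1088 genes of the real one at an unadjusted p under 0.05, up to 2014 (co-cultures 5 and 6 against the rest). For the NF-kB list, 2 of 28 splits gave a camera p as small (real 1.46e-12, co-cultures 3 and 6 against the rest 2.85e-13), while for the number of lists called at the preset correlation 1 of 28 splits, the real one, gave 15 and the next highest 12. The real split thus ranked first on this count, and 1 of 28 is the smallest share possible. But the count was chosen after the results were seen, beside the several others given here. Chance is therefore not excluded for it, and with an estimated correlation 0 lists were called. Scaling is argued against by a mean of at least 0.65 for the NF-kB list under median centring and quantile normalization. RNA of leftover CLL cells, which the CD19 beads were meant to remove, or of other leukocytes, which they do not target, stays open. Without the filter, the 47 B cell and pan-leukocyte markers had a median difference of 0.012 (95% bootstrap interval -0.032 to 0.17). The NF-kB median was higher, at 0.45 without the filter and 0.53 with it. The abundant B cell gene Cd74 had mean signals of 192 in mono-culture and 165 in co-culture. But only 17 of the 47 passed the filter, the monocyte and macrophage markers past the filter were higher (median 0.47, camera adjusted p = 0.0330, and 0.197 with an estimated correlation), although the median of all 25 such markers was 0.061, and binding of human RNA to mouse probes was not measured. Co-culture itself, and washing and bead steps that the mono-cultures may not have had, stay open.

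The lower 18S signal in co-culture was not shared by the 18 bacterial hybridisation controls, whose median log2 difference was -0.092 against -1.08 for 18S, which argues against scaling or hybridisation. The log2 actin 3'/5' ratio differed by 0.096, while the 3' and 5' probe sets of 18S differed by 0.53. The ratio covers actin only, and the mono-cultures themselves had unlogged ratios of 1.26 and 1.49. Shorter labelled fragments therefore stay open. How much ribosomal RNA was carried into the labelling was not tested, and no biological explanation was tested.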
